A study of Mus musculus with 8 samples.

How the data were processed

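RNA from 8 cultures of mouse embryonic stem cells was hybridised to 8 single-colour Agilent mouse arrays in 3 groups. Per the labels' protocols, total RNA was isolated on columns with a DNase step, and a fixed mass of it was labelled with a low-input amplification kit. The deposited spot intensity is the processed signal of Agilent Feature Extraction 11.0.1.1, a linear intensity after background subtraction, per the file headers. Per the labels the dye is Cy5, whereas the deposited files hold the green channel, and a single channel was used per array. The deposited value table holds 1 value per probe. These values equal the processed signal to 3 significant digits for 100% of probes, with a largest relative difference of 0.005, so its scale is linear and no centring was applied. Its column medians were 25.0, 50.8 and 29.3 for the untreated arrays, 14.1 and 16.3 for the vehicle arrays, and 15.8, 13.3 and 14.4 for the 4OHT arrays. Each array holds a single RNA, so no ratio direction had to be settled.

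The arrays hold 59305 spots that are not controls, for 55681 probes, and 3671 control spots. Control spots were left out of the tests. No spot was saturated (0 on the 8 arrays). Spots of 1 probe were averaged, and 466 probes were left out because an outlier-marked spot left an array without a value. Of these, 425 were lost to untreated replicate 2. Log2 processed signal minus the array's 75th percentile was used throughout, and all log2 values below are on that scale unless another is named. A probe was kept if it was well above background on every array of at least 1 group, which left 33008 probes. RefSeq accessions were matched without version numbers to a gene table of assembly GRCm38.p6, used for names only, while the file headers name mm9. A symbol was found for 27656 probes, covering 20972 symbols, and the remaining probes kept the name in the files. Of the symbols, 3773 had several kept probes, and each was represented by the probe with the highest mean over the 8 arrays. The 28491 features tested were 14930 symbols, 7407 probes named by a genomic interval and 6154 probes with other accessions. Below, "genes" counts these features unless symbols are named.

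Differences were tested with limma 3.58.1 in R 4.3.3, with lmFit and eBayes in 1 fit of the 3 groups over all 8 arrays (5 residual degrees of freedom). P-values are two-sided, Benjamini-Hochberg adjusted over the 28491 features, and called under 0.05. They measure the spread between arrays, which the design text calls biological replicates, and the number of arrays limits the precision. Errors of log2 differences are standard errors from that fit, with 3 untreated, 2 vehicle and 3 4OHT arrays. The median standard error was 0.17 for vehicle against untreated and for 4OHT against vehicle, and 0.15 for 4OHT against untreated. Where no array of a group was well above background, a difference is given as "at least N-fold". That bound sets the brighter group's mean against the mean, over the dim group's arrays, of the higher of the lowest signal well above background and the dim probe's own signal. No fold is given where both groups were below background.

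The following choices were made before the data were examined. The text names, per comparison, the 8 largest rises and 8 largest falls among called genes whose arrays do not overlap between the groups and which were well above background throughout the brighter group. It also names the fixed genes Nanog, Pou5f1, Sox2, Klf4, Esrrb, Gata6, Dusp6, Spry4, Egr1, Myc and Fos, and up to 2 rising and 2 falling called members of each gene list. Not every gene the rule allows is printed. Genes chosen after their values were seen are said to be so. A total of 25 gene lists was fixed, from immediate early genes to nuclear non-coding RNAs, and 18 genes are in more than 1 list. Each list was tested against all other genes with limma's camera (preset correlation 0.01), adjusted over the 25 lists of a comparison, and again with the correlation estimated from the arrays. Members matched through an older synonym stay in their list, which puts Mllt11 among the Zfp genes and Eif1a among the two-cell-like state genes.

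The alternatives were normexp background correction with an offset of 50, quantile normalization, scaling to each array's median, no scaling, and scaling to spike-in probes. The deposited value table, no filter, a filter over all 8 arrays, and the mean of a gene's probes were also run, as were trended and robust eBayes, a fit of only the groups compared, a replicate block, a 2-fold minimum and leaving out each array. Normexp used the median spot and background signals, since the files hold no mean signal. Spike-in scaling subtracts, per array, the mean of 8 of the 10 Agilent E1A control probes. Agilent's controls of this kind are meant to be added to the RNA before labelling, and the labels do not describe that step. A fixed mass of total RNA was labelled, so this scale follows signal per mass of total RNA and not per cell. Cyclic loess was chosen after seeing the data. Slide could not be fitted as a block for the 4OHT comparisons, because slide 1 holds all 4OHT arrays and slide 2 all others.

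The procedure was tested on simulated data with the real signal levels, in which 200 of the 28491 features were changed. For 4OHT against vehicle it recovered 0% of 1.5-fold, 39.0% of 2-fold and 81.5% of 4-fold changes, with 4 and 10 unchanged features called at the latter 2 sizes. For vehicle against untreated it recovered 0%, 44.5% and 76.0%, and for 4OHT against untreated 0%, 49.5% and 83.0%. More genes than the 200 changed here were called in every real comparison, which eases the adjusted threshold, so these shares do not carry over. Against untreated, 2808 of the 11831 genes called higher with vehicle changed at least 2-fold, so smaller changes were called too. In the vehicle design, camera called 50 of 50 simulated lists of 25 genes shifted by 0.30 log2 and 1 of 50 unshifted lists. Simulated genes varied independently, whereas the correlation estimated for ribosomal protein genes was 0.68, so camera was not tested on correlated lists.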

Results

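The expression of mRNA was measured on 8 arrays in mouse embryonic stem cells, pluripotent cells grown here with LIF, a cytokine that sustains self-renewal, and 250 nM PD173074, an inhibitor of FGF receptors. In 3 cultures the cells were left untreated (0 h), as their treatment label and description state, although their titles also carry an abbreviation of actinomycin D. Every comparison with untreated rests on that label. In the other cultures 5 µM actinomycin D, which blocks transcription, was followed 30 min later by 4 h of ethanol vehicle (2 arrays) or of 250 nM 4-hydroxytamoxifen (4OHT, 3 arrays). The design text states 3 biological replicates per condition, and 2 vehicle arrays are used here. The labels do not state what 4OHT acts on in these cells. The title of the series concerns mRNA degradation regulated by Erk, the kinase downstream of FGF receptors.

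Signal was lower on every array that followed actinomycin D. The 75th percentile of the processed signal was 333, 457 and 405 on the untreated arrays, 166 and 205 on the vehicle arrays, and 209, 180 and 182 on the 4OHT arrays. Spots well above background made up 67.3, 75.7 and 61.0% of the untreated, 60.0 and 55.6% of the vehicle, and 57.4, 54.7 and 53% of the 4OHT arrays. Relative to the spike-in probes, the log2 75th percentile was 8.87 ± 0.09 (SD, n = 3) untreated, 7.59 ± 0.08 (SD, n = 2) with vehicle and 7.29 ± 0.25 (SD, n = 3) with 4OHT. That scale put the vehicle arrays 2.42-fold and the 4OHT arrays 3.00-fold below untreated at this percentile. The single spike-in probes differed by −0.08 to 0.32 between vehicle and untreated, by −0.09 to 0.56 between 4OHT and vehicle and by 0.09 to 0.79 between 4OHT and untreated, so this scale carries an error of its own, and both comparisons with 4OHT are between slides. Log2 differences below are relative to each array's 75th percentile, so a rise there can be a smaller loss than that of the 75th percentile. Untreated replicate 2 had the highest low-end signal, with a 25th percentile of 12.6 against 4.13 and 4.24, and 466 non-uniform probes. The scanner's spread metric was out of range on both vehicle arrays (9.42 and 8.20%). On vehicle replicate 1 the median coefficient of variation of replicated non-control probes was 20.5%, against 11.9 to 14.3% on the other arrays. Correlations across genes were 0.987 to 0.994 within groups and 0.956 to 0.990 between groups, and genes are not independent replicates.

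**Figure D1:**
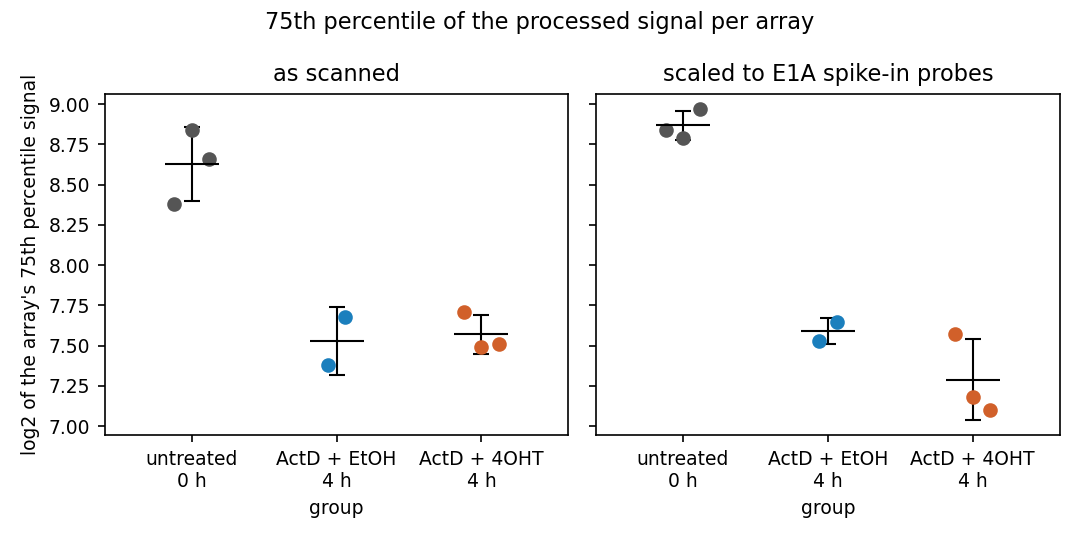
The 75th percentile of processed signal per array (log2), as scanned and relative to the spike-in probes, for the untreated, vehicle and 4OHT groups, with points for arrays and bars for the mean ± SD. Relative to the spike-in probes the group means were 8.87, 7.59 and 7.29.

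Vehicle against untreated shows which mRNAs were depleted after 30 min of actinomycin D and a further 4 h with vehicle. Fos, an immediate early transcription factor, fell at least 10-fold (adjusted p = 5.5e-06) to below background, and Myc, a growth regulator, fell by 4.72 ± 0.13 log2 (adjusted p = 3.7e-06). Dusp6, a phosphatase that inactivates ERK, fell by 4.85 ± 0.22 (adjusted p = 2.1e-05), while Spry4, a feedback inhibitor of the same pathway, fell at least 18.2-fold (adjusted p = 0.00018). The pluripotency factors parted: Klf4 fell by 3.61 ± 0.12 (adjusted p = 6.8e-06) and Sox2 by 3.54 ± 0.13 (adjusted p = 8.8e-06), whereas Pou5f1 rose by 1.0 ± 0.13 (adjusted p = 0.00082; −0.28 on the spike-in scale).

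Among immediate early genes, 19 of 26 fell, with Egr1 at −3.68 ± 0.22, and 1 rose (adjusted over the list alone, 20 and 1). The riser was Srf, which encodes a transcription factor of the immediate early response (0.54 ± 0.12; −0.74 on the spike-in scale). The list's median was −2.33 (camera adjusted p = 1.8e-13; adjusted p = 0.016 with an estimated correlation). Of 21 ERK pathway feedback genes, 15 fell, with Spry1 at −4.81 ± 0.28, and 3 rose, with the same counts adjusted over the list alone. The risers were Ccnd1, a G1 cyclin (0.99), Emp1 (0.87) and, chosen after its values were seen, Etv5 (0.69), and all 3 were below untreated on the spike-in scale (−0.29, −0.41 and −0.59). Without vehicle replicate 2, Emp1 no longer passed (0.67, adjusted p = 0.058), and Etv5 was also below untreated with quantile (−0.20), unscaled (−0.41) and cyclic loess (−0.14) values. The median was −1.89 (camera adjusted p = 3.1e-08; adjusted p = 0.016 with an estimated correlation). Of 16 Id and BMP or TGF-beta response genes, 13 fell and 0 rose on both adjustments (median −1.78; camera adjusted p = 1.4e-10; adjusted p = 0.045 with an estimated correlation), among them Lefty1, a secreted Nodal inhibitor, by 4.06 ± 0.44. The 388 Zfp zinc finger genes held 276 that fell and 42 that rose, 280 and 45 adjusted over the list alone (median −1.16; camera adjusted p = 1.6e-33; adjusted p = 0.016 with an estimated correlation). Zfp296 fell by 5.23 ± 0.11.

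Of 26 naive pluripotency genes, 11 fell and 7 rose, the same adjusted over the list alone, and 23 fell and 0 rose on the spike-in scale (median −0.14, −1.42 on the spike-in scale; camera adjusted p = 0.0018; adjusted p = 0.066 with an estimated correlation). Socs3, an inhibitor of LIF signalling, fell by 4.81 ± 0.21 and Gbx2, a homeobox factor, by 4.38 ± 0.24. Esrrb, an orphan nuclear receptor, rose by 0.30 ± 0.10 (adjusted p = 0.04) but was below untreated with quantile (−0.64), unscaled (−0.80), spike-in (−0.98) and cyclic loess (−0.56) values. Its call held without untreated replicate 1 but without no other array (0.24 to 0.36, adjusted p from 0.055 to 0.17). Nanog did not pass the test on its brightest probe (0.00 ± 0.12, adjusted p = 0.99), which was below untreated on the spike-in scale (−1.28), and its other probe read 1.62. Of 21 core pluripotency genes, 12 rose and 6 fell, the same adjusted over the list alone. This list's median was 0.54, its mean −0.43 and its test direction down (camera adjusted p = 0.53), with a median of −0.73 on the spike-in scale. Foxd3 fell by 4.72 ± 0.20 and Nodal, a TGF-beta family signal, by 4.51 ± 0.12, while Dppa5a rose by 1.15 ± 0.12 (−0.12 on the spike-in scale). Of 16 primed epiblast genes, 9 fell and 2 rose on both adjustments (median −1.03; camera adjusted p = 0.00012; adjusted p = 0.12 with an estimated correlation).

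Among the fixed gene lists, those of ribosomal protein, glycolysis and respiratory chain genes had the highest medians. On the spike-in scale these medians were below untreated. Single genes outside these lists rose further, such as Rnu3b1 (3.61). Of 86 ribosomal protein genes 82 rose, Rpl36a by 1.40 ± 0.11. The median was 1.15, against −0.13 on the spike-in scale (camera adjusted p = 1.8e-13; adjusted p = 0.39 with an estimated correlation). Of 79 respiratory chain and ATP synthase genes 77 rose, Cox6c by 1.37 ± 0.13, and 0 fell (median 0.99, −0.29 on the spike-in scale; camera adjusted p = 1.8e-13; adjusted p = 0.17 with an estimated correlation). Of 18 glycolysis genes 14 rose, Gapdh by 1.33 ± 0.13, and 0 fell (median 1.14, −0.14 on the spike-in scale; camera adjusted p = 0.0018; adjusted p = 0.14 with an estimated correlation). For these 3 lists the counts adjusted over the list alone were the same. Of 28 DNA replication genes, 22 rose and 2 fell, 23 and 2 adjusted over the list alone (median 0.71, −0.57 on the spike-in scale; camera adjusted p = 0.013; adjusted p = 0.27 with an estimated correlation). The fallers were the licensing factors Cdc6 (by 1.90 ± 0.14, with −0.19 on its other probe) and Cdt1 (by 1.67 ± 0.12).

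Histone genes fell in 26 of 43 cases, with H1f5 at −5.11 ± 0.14 and H2ac4 at −4.48 ± 0.10, and rose in 6, with the same counts adjusted over the list alone (median −1.12; camera adjusted p = 1.2e-09; adjusted p = 0.078 with an estimated correlation). Of 25 p53 targets, 13 fell and 5 rose, 13 and 6 adjusted over the list alone (median −0.56; camera adjusted p = 5.4e-05; adjusted p = 0.069 with an estimated correlation). Cdkn1a, a cell cycle inhibitor, fell by 2.84 ± 0.11, and Bax, a pro-apoptotic factor, rose by 0.99 ± 0.11 (−0.28 on the spike-in scale). Of 17 nonsense-mediated decay targets, 8 fell, Trib3 by 2.30 ± 0.20, and 5 rose, 9 and 5 adjusted over the list alone (median −0.69; camera adjusted p = 0.02; adjusted p = 0.12 with an estimated correlation). Of 9 nuclear non-coding and host RNAs, 5 fell, Snhg12 by 2.03 ± 0.13 and Malat1 by 1.76 ± 0.26, and 2 rose on both adjustments (median −0.72; camera adjusted p = 0.013; adjusted p = 0.17 with an estimated correlation). On the spike-in scale the medians of the 10 lists called down ran from −3.60 to −1.42, and 0 members of any of the 25 lists were called higher.

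Camera did not call the other lists. The 49 mRNA decay machinery genes had 30 rises and 12 falls, 30 and 13 adjusted over the list alone (median 0.47, −0.81 on the spike-in scale; camera adjusted p = 0.93). Btg1, an antiproliferative factor, fell by 4.80 ± 0.13, with −0.91 on its other probe. Of 19 AU-rich element binding protein genes, 11 rose and 6 fell (median 0.52, mean −0.04, test direction down, median −0.76 on the spike-in scale; camera adjusted p = 0.9). Zfp36, which promotes decay of AU-rich mRNAs, fell at least 3.53-fold (adjusted p = 0.00012) and Zfp36l2 by 2.96 ± 0.09, while Elavl1, which stabilises such mRNAs, rose by 1.05 ± 0.08 (−0.22 on the spike-in scale). The 26 G2 and mitosis genes had 13 rises and 2 falls, of the kinases Plk1 (by 0.83) and Aurka (by 0.38, not called without untreated replicate 2 or either vehicle array, adjusted p from 0.051 to 0.089), with a median of 0.41 (−0.87 on the spike-in scale; camera adjusted p = 0.19). Cholesterol synthesis genes rose in 10 of 22 cases, 13 adjusted over the list alone, and 2 fell on both adjustments, with Sqle at −1.04 (median 0.55, −0.73 on the spike-in scale; camera adjusted p = 0.53). Chaperone genes rose in 10 of 15 cases, and Dnajb1 (by 3.68) and Hspa1a (by 1.68) fell (median 0.91, −0.37 on the spike-in scale; camera adjusted p = 0.2).

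Lineage lists were not called either. Of 22 primitive endoderm genes, 7 fell and 6 rose (median 0.17, mean −0.46, test direction down, median −1.10 on the spike-in scale; camera adjusted p = 0.094). Gata6 fell at least 2.23-fold (adjusted p = 0.022; 0.40 with normexp), a call lost without untreated replicate 3 (adjusted p = 0.059) or vehicle replicate 1 (0.068) or 2 (0.096), and Sox7 at least 7.13-fold (adjusted p = 0.00028). Of 12 mesendoderm and neuroectoderm markers, 4 rose and 3 fell (median 0.10, mean −0.17, test direction down, median −1.18 on the spike-in scale; camera adjusted p = 0.51). Of 11 trophoblast markers, 2 fell, Gata3 by 2.44 ± 0.24 and Ascl2 by 1.74 ± 0.11, and 0 rose (median 0.13, mean −0.05, test direction down, median −1.14 on the spike-in scale; camera adjusted p = 0.077). Feeder fibroblast markers rose in 5 of 14 cases and Twist1 fell (adjusted p = 0.013), with no size given because it was well above background on 1 of 2 vehicle arrays (0.27 with normexp; list median 0.73, −0.55 on the spike-in scale; camera adjusted p = 0.53). Of 6 two-cell-like state genes, 3 rose and Eif1a, a translation initiation factor, fell by 0.65 ± 0.10 (median 0.91, −0.37 on the spike-in scale; camera adjusted p = 0.69). In these lists, and in the AU-rich, mitosis and chaperone lists, the counts adjusted over the list alone were the same.

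Over all genes, 11831 were higher and 4539 lower with vehicle than untreated, 6175 and 2851 of them with a symbol, and 2808 and 2970 changed at least 2-fold. The largest falls included Fam43a (at least 54.4-fold) and Snai1, a transcriptional repressor (at least 27.2-fold). Rnu3b1, a small nucleolar RNA, rose by 3.61 ± 0.15 and stayed above untreated on the spike-in scale (2.34), as did Galns, a lysosomal sulfatase (2.0 and 0.73), and Gata5 (1.91 and 0.63). The split depends on the scale: 72.3% of called genes were higher relative to the 75th percentile (all-gene median 0.40), and 0.2% (32 higher, 18528 lower) relative to the spike-in probes (all-gene median −0.88). The share was 84.8% with normexp, 61.5% with quantile, 45.0% with cyclic loess and 0.3% with unscaled values. The vehicle and untreated arrays shared slide 2 but lay in different rows of it, so row and treatment cannot be told apart.

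**Figure D2:**
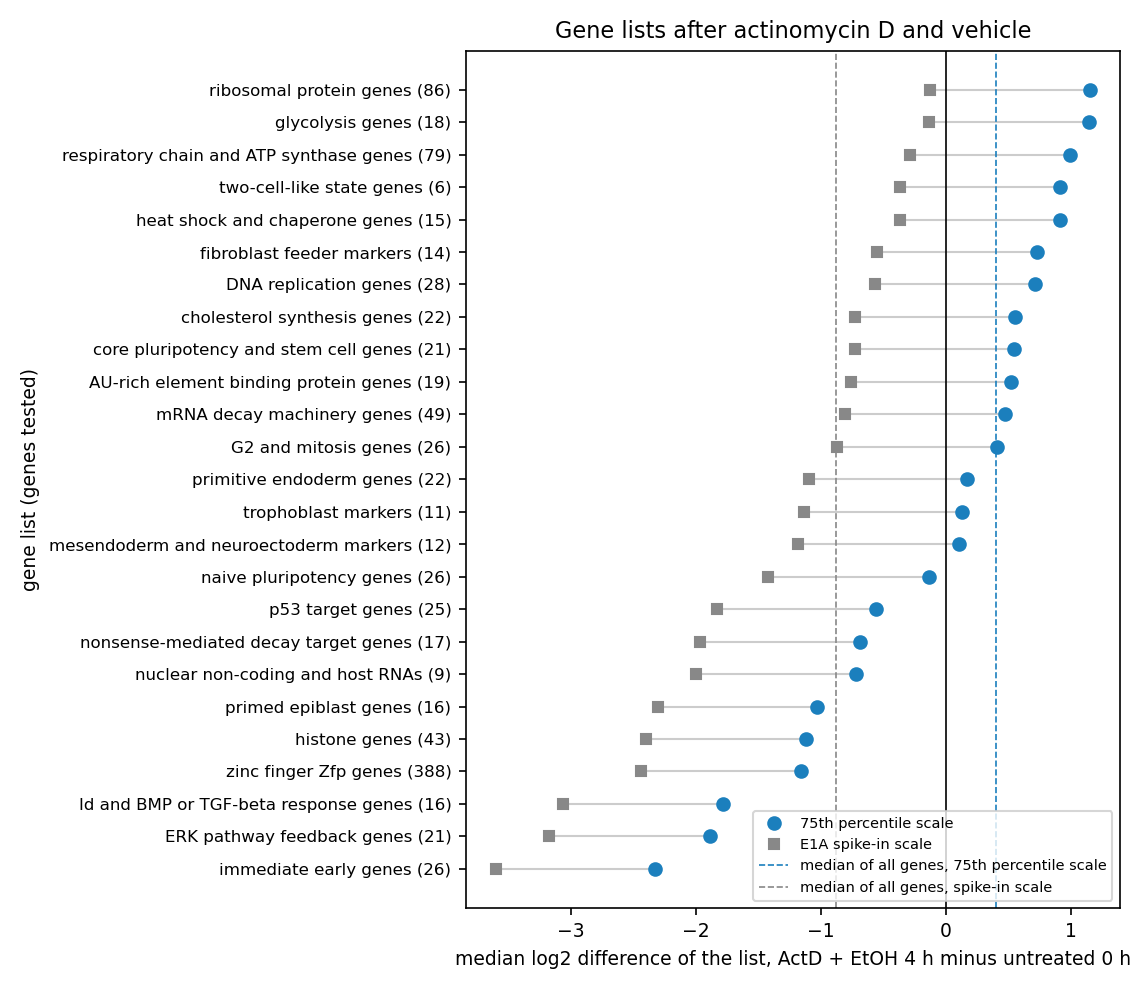
Median log2 difference of each of the 25 gene lists, vehicle against untreated, relative to the 75th percentile and to the spike-in probes, with dashed lines at the all-gene medians (0.40 and −0.88). The ribosomal protein, respiratory chain, glycolysis and DNA replication lists lie above 0 on the first scale (1.15, 0.99, 1.14 and 0.71) and below 0 on the second (−0.13, −0.29, −0.14 and −0.57).

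4OHT against vehicle, with actinomycin D in both, is the comparison closest to the series title, since it asks which mRNAs differ with 4OHT while transcription is blocked. Hbegf, an EGF receptor ligand, was higher by 2.17 ± 0.10 (adjusted p = 0.0016), at 2.01 untreated, −0.15 with vehicle and 2.02 with 4OHT. Epha2, an ephrin receptor kinase, was higher by 2.54 ± 0.17 (adjusted p = 0.0029), at 3.93, 0.72 and 3.26, and Pim3, a serine/threonine kinase, by 2.34 ± 0.10 (adjusted p = 0.0016), at 4.18, 0.09 and 2.43. Mllt11 (2.70 ± 0.24, adjusted p = 0.0064), Rab3a, a vesicle GTPase (2.23 ± 0.11, adjusted p = 0.0016), Rusc2 (2.21 ± 0.12, adjusted p = 0.0019) and Pdk4, a mitochondrial kinase (2.17 ± 0.16, adjusted p = 0.0042), were also higher. Prob1 was at least 2.83-fold higher (adjusted p = 0.0075), being well above background on the 4OHT arrays only. Apart from Prob1, which has only that bound, all of these were higher on the spike-in scale too (1.86 to 2.40).

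The genes lower with 4OHT that were measured on all arrays were chosen after their values were seen. They include Med4, a Mediator subunit, which fell by 1.81 ± 0.14 (adjusted p = 0.0042, with −0.55 on its other probe), and Slbp, which binds histone mRNA stem-loops, by 1.74 ± 0.16 (adjusted p = 0.0065, with −1.50 on its other probe). Rit1, a Ras-family GTPase, fell by 1.68 ± 0.11 (adjusted p = 0.0024), Ctdp1, an RNA polymerase II phosphatase, by 1.67 ± 0.13 (adjusted p = 0.0042), and Bmf, a pro-apoptotic factor, by 1.68 ± 0.19 (adjusted p = 0.01). The largest falls by the naming rule included the dim receptor genes Tas2r118 (at least 1.80-fold) and Fpr-rs6 (at least 2.37-fold). Both were well above background on every untreated and vehicle array, all on slide 2, and on no 4OHT array, all on slide 1. The same held for Tm4sf19, Scgb2b2, Azgp1 and Gpr31b, which the rule also named. Of the 734 genes called lower with 4OHT, 69 were well above background on slide 2 only, against 307 of the 28491 tested. Whether this follows the slide or 4OHT cannot be told apart.

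Most pluripotency and ERK pathway genes did not pass the test. Nanog stood at 0.47 ± 0.12 (adjusted p = 0.098), Klf4 at −0.53 ± 0.12 (adjusted p = 0.072), Sox2 at −0.52 ± 0.13 (adjusted p = 0.088) and Pou5f1 at −0.08 ± 0.13 (adjusted p = 0.8). Dusp6 stood at 0.64 ± 0.22 (adjusted p = 0.19; 1.03 and 0.048 without vehicle replicate 2), Egr1 at −0.08 ± 0.22 (adjusted p = 0.89) and Myc at −0.20 ± 0.13 (adjusted p = 0.47). Spry4 was below background on both vehicle arrays and on all but 1 of the 4OHT arrays, so no fold is given (adjusted p = 0.48). Of 26 naive pluripotency genes, 2 rose and 2 fell, 6 and 4 adjusted over the list alone. The risers were Fgf4, an FGF ligand (1.36 ± 0.14, adjusted p = 0.009), and Mras (0.66 ± 0.12, adjusted p = 0.032, with 0.33 and 0.13 on its other probes), and the fallers Klf5 (by 0.70 ± 0.11, adjusted p = 0.027) and Esrrb (by 0.63 ± 0.10, adjusted p = 0.028). Of 21 ERK pathway feedback genes, 1 rose and Etv5 fell (by 0.53 ± 0.11, adjusted p = 0.046), 3 and 2 adjusted over the list alone. Of 26 immediate early genes, Ier3 rose (1.33 ± 0.21, adjusted p = 0.025), Fos passed the test upwards but was below background in both groups, and Egr4 fell at least 2-fold (adjusted p = 0.034), which makes 2 and 1, or 2 and 2 adjusted over the list alone. Gata6 was below background in both groups.

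Camera called 3 of the 25 lists with the preset and 0 with an estimated correlation, where adjusted p ran from 0.76 to 0.93. Of 25 p53 targets, 5 rose and 2 fell, 8 and 3 adjusted over the list alone and 1 and 2 on the spike-in scale (median 0.20, −0.11 on the spike-in scale; camera adjusted p = 0.0024; adjusted p = 0.76 with an estimated correlation). The risers were Plk3, a stress-responsive kinase (2.10 ± 0.17), the death receptor Tnfrsf10b (0.86 ± 0.10), the growth arrest gene Gadd45a (0.82 ± 0.10) and, chosen after their values were seen, Mdm2, which targets p53 for degradation (0.82 ± 0.13), and Cdkn1a (0.58 ± 0.11). Cdkn1a was no longer called when any 1 of the 3 4OHT arrays was left out (adjusted p from 0.088 to 0.12). The call of Mdm2 was lost without 4OHT replicate 2 (0.086) or 3 (0.073). Bbc3, a pro-apoptotic factor, fell by 1.54 ± 0.19 and Sesn2 by 0.71 ± 0.10. Ribosomal protein genes had a median of −0.17 with 0 of 86 called on either adjustment (camera adjusted p = 0.0021; adjusted p = 0.85 with an estimated correlation). Histone genes had a median of −0.32 (camera adjusted p = 0.0021; adjusted p = 0.85 with an estimated correlation), with H2ac4 alone called (fell by 0.52 ± 0.10), and 5 fallers adjusted over the list alone. Of 49 mRNA decay machinery genes 5 fell and 0 rose, 7 and 0 adjusted over the list alone and 3 and 0 on the spike-in scale, and the list was not called (median −0.04; camera adjusted p = 0.72). The exosome subunits Exosc1 (by 1.05), Exosc4 (by 0.79) fell and, chosen after their values were seen, so did the exosome subunit Exosc6 (by 0.57), the deadenylase subunit Cnot2 (by 0.67) and Lsm1 (by 0.49). Exosc6, Cnot2 and Lsm1 each lost the call when any 1 of the 3 4OHT arrays was left out (adjusted p from 0.068 to 0.14). Exosc1 lost it without 4OHT replicate 2 (0.065) or 3 (0.055), and Exosc4 without 4OHT replicate 2 (0.062). Of 388 Zfp genes, 14 fell and 7 rose, 20 and 13 adjusted over the list alone (camera adjusted p = 0.42). Of 19 AU-rich element binding protein genes 1 rose and 1 fell on both adjustments, and 0 and 1 on the spike-in scale (median 0.05; camera adjusted p = 0.42). The riser was Zfp36l1, which promotes mRNA decay (0.99 ± 0.17). It was no longer called when untreated replicate 1 or any 1 of the 3 4OHT arrays was left out (adjusted p from 0.059 to 0.1). Single members fell in other lists, such as Sox4 (by 1.0), Id2 (by 0.95), Eif1a (by 1.18) and Cdt1 (by 1.18), and both Plk1 (by 1.12) and Ccna2 (by 1.06) among mitosis genes.

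**Figure D3:**
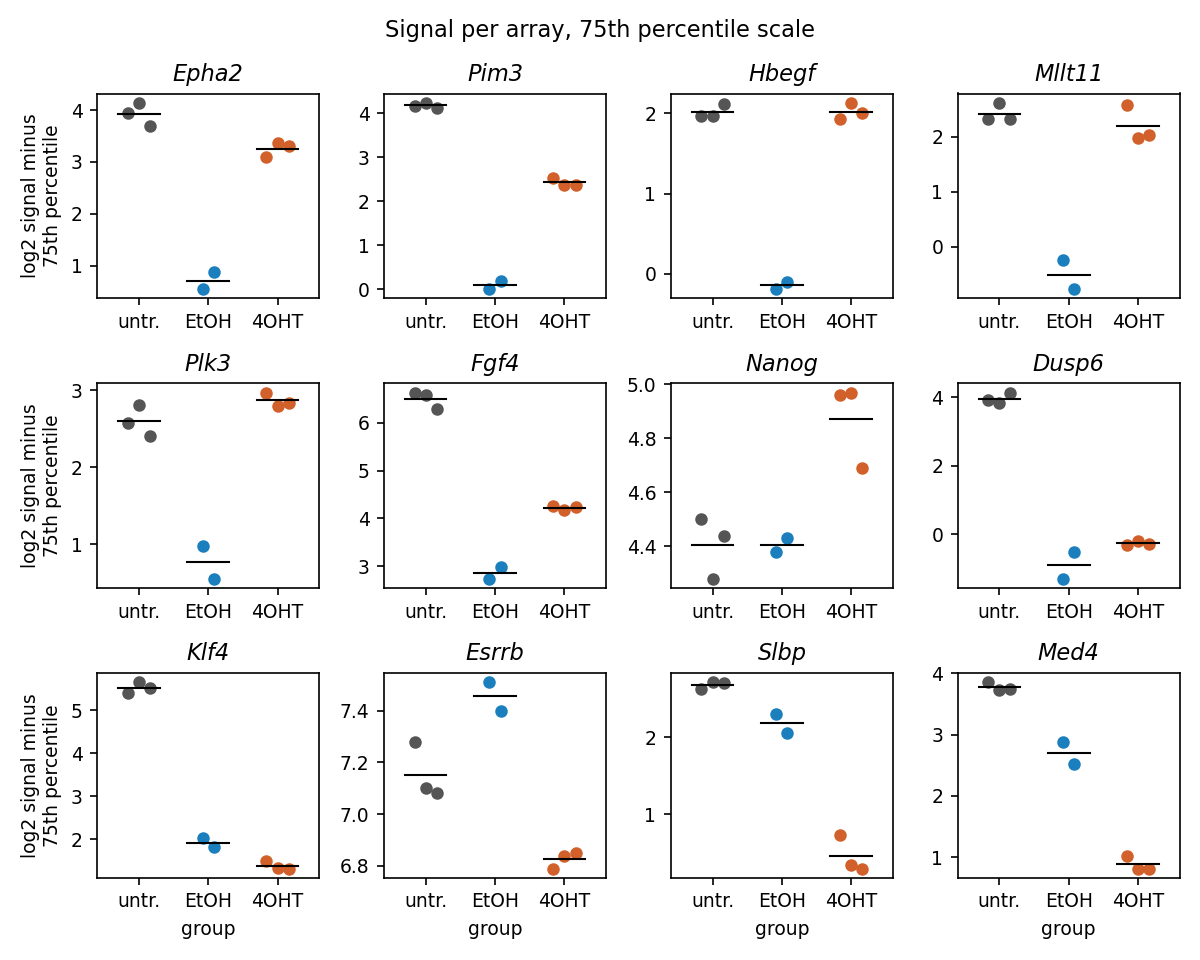
Log2 signal relative to the 75th percentile on each array for 12 genes, with points for arrays and lines for the means of the untreated, vehicle and 4OHT groups. Hbegf stood at 2.01, −0.15 and 2.02 in the 3 groups, whereas Klf4 stood at 5.52, 1.92 and 1.38.

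In all, 263 genes were higher and 734 lower with 4OHT (198 and 459 with a symbol), 78 and 290 of them at least 2-fold. The share of higher calls was 26.4%, and 3.2% (39 and 1179) on the spike-in scale, with all-gene medians of −0.05 and −0.36. All 4OHT arrays were on slide 1 and all vehicle arrays on slide 2, so slide and 4OHT cannot be told apart. With the replicate number as a block, 8 genes were higher and 12 lower. The counts also depend on the processing (78 and 163 scaled to the median, 17 and 75 unscaled, 25 and 76 without the filter, 18 and 48 with only the groups compared) and on single arrays: they were 123 and 378, 102 and 348 without untreated replicate 1 or 3, 60 and 81, 165 and 253 without vehicle replicate 1 or 2, and 119 and 415, 50 and 182, 69 and 308 without 4OHT replicate 1, 2 or 3. Of the 43 called genes named for this comparison, 14 passed without each array in turn (Epha2, Pim3, Hbegf, Mllt11, Rab3a, Rusc2, Pdk4, Plk3, Eif1a, Med4, Slbp, Rit1, Ctdp1 and Tas2r118), and the other 29 all lost the call without vehicle replicate 1.

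4OHT against untreated sets mRNA levels after actinomycin D and 4OHT against those at 0 h, again without a 4 h culture free of actinomycin D. Myc fell by 4.91 ± 0.11 (adjusted p = 1.2e-06), Dusp6 by 4.21 ± 0.20 (adjusted p = 1.1e-05), Klf4 by 4.14 ± 0.11 (adjusted p = 1.7e-06), Sox2 by 4.06 ± 0.12 (adjusted p = 2.3e-06) and Egr1 by 3.76 ± 0.20 (adjusted p = 1.7e-05). Fos fell at least 8.56-fold (adjusted p = 4.6e-06) and Spry4 fell too (adjusted p = 0.00011), with no size given because it was well above background on 1 of 3 4OHT arrays. Esrrb fell by 0.33 ± 0.09 (adjusted p = 0.018), though not past the threshold without 4OHT replicate 1 (adjusted p = 0.053) or 2 (0.051). Nanog rose by 0.47 ± 0.11 (adjusted p = 0.0089) but was below untreated with quantile (−0.05), unscaled (−0.59), spike-in (−1.12) and cyclic loess (−0.10) values, whereas its other probe read 2.04, and 0.46 on the spike-in scale. Pou5f1 rose by 0.91 ± 0.12 (adjusted p = 0.00059) with −0.14 unscaled and −0.67 on the spike-in scale. Gata6 fell at least 1.90-fold (adjusted p = 0.0025; 0.32 with normexp). The largest falls included Fam43a (at least 46.4-fold), Chac1, a glutathione-degrading enzyme (at least 54.5-fold), Zfp296 (by 5.52 ± 0.09), H1f5 (by 5.49 ± 0.12) and Btg1 (by 5.41 ± 0.12, with −1.04 on its other probe). The largest rises included Rnu3b1 (3.78 ± 0.13), Timmdc1 (2.39 ± 0.14), Galns (2.37 ± 0.15), Gata5 (2.27 ± 0.13) and Prob1 (at least 4.54-fold). Apart from Prob1, which was below background in untreated, each was above untreated on the spike-in scale too (0.69 to 2.20), except that the other probe of Timmdc1 read 0.60, and −0.99 on the spike-in scale.

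Camera called 14 lists, 10 down and 4 up, and 4 with an estimated correlation. Those 4 were immediate early genes (20 of 26 fell, 2 rose; 22 and 2 adjusted over the list alone; adjusted p = 0.023 with an estimated correlation), ERK pathway feedback genes (15 of 21 fell, 2 rose on both adjustments; adjusted p = 0.023 with an estimated correlation), Id and BMP or TGF-beta response genes (16 of 16 fell on both adjustments; adjusted p = 0.039 with an estimated correlation) and Zfp genes (281 of 388 fell, 43 rose; 283 and 43 adjusted over the list alone; adjusted p = 0.023 with an estimated correlation). Of the lists called up, ribosomal protein genes rose in 82 of 86 cases (median 0.99, −0.59 on the spike-in scale; adjusted p = 0.42 with an estimated correlation) and respiratory chain genes in 76 of 79 (0.97, −0.61 on the spike-in scale; adjusted p = 0.17 with an estimated correlation). Adjusted over the list alone these counts were 82 and 78, while on the spike-in scale 0 rose in either list and 81 and 70 fell. Glycolysis genes had a median of 0.95 (−0.63 on the spike-in scale; camera adjusted p = 0.0043; adjusted p = 0.17 with an estimated correlation) and DNA replication genes 0.61 (−0.98 on the spike-in scale and −0.04 with quantile values; camera adjusted p = 0.036; adjusted p = 0.36 with an estimated correlation). The naive pluripotency, primed epiblast, p53 target, histone, nonsense-mediated decay and nuclear RNA lists were called down with the preset correlation only, with adjusted p from 0.099 to 0.17 with an estimated correlation.

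Against untreated, 11692 genes were higher and 5342 lower with 4OHT, 2412 and 3461 of them at least 2-fold. Higher calls made up 68.6% relative to the 75th percentile and 0.1% (29 and 26622) relative to the spike-in probes, with all-gene medians of 0.31 and −1.27. The share was 84.4% with normexp, 46.6% with cyclic loess and 0.6% with unscaled values. Both comparisons with untreated share their 3 control arrays. Their log2 differences correlated at 0.90 across 28491 genes, against 0.45 in 100 simulations of unchanged groups with these controls, and the covariance was 0.86 against 0.041. Of the called genes, 10127 were higher in both (4855 for independent lists) and 3932 lower in both (851 for independent lists), with 76 in opposite directions. The simulated correlation and covariance already include the shared controls, with noise that is independent between genes. The counts for independent lists do not include them. The 3 controls cannot be split into 2 sets of 2 or more, so part of the excess over independent lists may come from the shared controls. Slide and treatment cannot be told apart here either, with all untreated arrays on slide 2.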

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

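Cyclic loess was the only test in this part chosen after the result was seen. Counts are given as higher and lower genes, for vehicle against untreated, then 4OHT against vehicle, then 4OHT against untreated, and where they moved by over 1.5 times the cause was not tested unless it is given. Using the deposited value table, a filter over all 8 arrays, or the mean of a gene's probes moved none of these counts by that much. Leaving out each array gave 9555 to 11832 higher and 3896 to 4584 lower, 50 to 201 and 81 to 561, and 10318 to 11750 and 4789 to 5419, with a lone vehicle array assumed to vary like the other groups. Of the named genes called, 38 of 55, 7 of 43 and 17 of 21 kept direction and call in every setting that tested them, and 44, 43 and 18 reversed in none of those. The filter over all 8 arrays leaves out genes dim in a group, and the 2-fold minimum was applied to counts and not to single genes. Leaving out an array reversed 0 of them, and 51, 14 and 20 kept the call without each array in turn. The 7 genes called in each of these settings for 4OHT against vehicle were Epha2, Pim3, Rab3a, Rusc2, Hbegf, Rit1 and Ctdp1. The dimmest spots limit these results, since 53 to 75.7% of spots were well above background and the filter left 28491 features of the 48602 tested without it. Slide as a block was not run, because it cannot be separated from 4OHT.

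Normexp gave 19425 higher genes in the first comparison, 20018 in the third and 5 called lists in the second, and turned Gata6 (0.40 with vehicle, 0.32 with 4OHT) and Twist1 (0.27 with vehicle). Of the 4539 genes lower in the first comparison, normexp called 2871 lower and 771 higher. Of the 5342 genes lower in the third, it called 3262 lower and 1109 higher. Quantile normalization gave 7602 higher in the first and 434 lower in the second, and turned Esrrb (−0.64) and Etv5 (−0.20) with vehicle and, with 4OHT against untreated, Nanog (−0.05) and the median of DNA replication genes (−0.04). Scaling to each array's median gave 7362 higher in the first, 78 and 163 in the second, and 1 called list there. No scaling gave 35 and 13090, 17 and 75, and 95 and 15796. It turned Srf (−0.56), Ccnd1 (−0.11), Emp1 (−0.23), Esrrb (−0.80), Pou5f1 (−0.10), Elavl1 (−0.04), Bax (−0.10) and Etv5 (−0.41) with vehicle, and Nanog (−0.59) and Pou5f1 (−0.14) with 4OHT against untreated. Cyclic loess gave 4780 higher in the first and 5767 in the third, and turned Esrrb (−0.56) and Etv5 (−0.14) with vehicle and Nanog (−0.10) with 4OHT against untreated.

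Scaling to the spike-in probes gave 32 and 18528, 39 and 1179, and 29 and 26622, and the cause was not tested. The spike-in probes were brighter on the 4OHT arrays (mean 0.28) than on the vehicle (−0.06) and untreated arrays (−0.24), all in log2, while the log2 75th percentile as scanned was 7.57, 7.53 and 8.63. It turned Srf (−0.74), Ccnd1 (−0.29), Emp1 (−0.41), Esrrb (−0.98), Pou5f1 (−0.28), Dppa5a (−0.12), Elavl1 (−0.22), Bax (−0.28) and Etv5 (−0.59) with vehicle, and Nanog (−1.12) and Pou5f1 (−0.67) with 4OHT against untreated. With vehicle, it turned the medians of ribosomal protein (−0.13), respiratory chain and ATP synthase (−0.29), DNA replication (−0.57) and glycolysis genes (−0.14). With 4OHT against untreated, the same lists stood at −0.59, −0.61, −0.98 and −0.63, and p53 targets stood at −0.11 with 4OHT against vehicle.

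A minimum of 2-fold left 2808 and 2970, 78 and 290, and 2412 and 3461. For 4OHT against vehicle, no filter gave 25 and 76 with 5 called lists, trended and robust eBayes 418 higher, and the fit of only the groups compared 18 and 48, with fewer arrays to estimate the spread. The mean of its probes put Nanog at 0.81 with vehicle. With an estimated correlation, camera called 4, 0 and 4 lists in place of 14, 3 and 14. The groups share replicate numbers, and same-numbered arrays deviated together at correlations of −0.19 to 0.36. Vehicle and 4OHT arrays of the same number stood at 0.36 and 0.22. Deviations from the mean of so few arrays are tied to each other, so these correlations cannot decide whether the numbers pair the samples. With the replicate number as a block, 8 genes were higher and 12 lower for 4OHT against vehicle, and the other comparisons stayed within 1.5 times (10732 and 4321, 11194 and 5270).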

Other observations

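The tests chosen only after the result was seen are those of intensity-dependent scaling, of further or slower loss with 4OHT, and of the scaling to the 75th percentile. Transcript classes differed in brightness, with median signals of −2.81 for long non-coding, −0.51 for pseudogene and 0.59 for protein-coding transcripts relative to the 75th percentile, and their differences were not tested against each other. With vehicle against untreated, 388 long non-coding RNA genes had a median of 0.21 (−1.07 on the spike-in scale), with 120 higher and 76 lower. The 114 transcribed pseudogenes had a median of 0.57 (−0.71 on the spike-in scale), with 58 higher and 12 lower, and 14416 protein-coding genes had 0.35 (−0.92 on the spike-in scale). With 4OHT against untreated these medians were 0.00, 0.58 and 0.33 (−1.58, −1.0 and −1.25 on the spike-in scale).

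Several mRNAs stood near their untreated level with 4OHT and below it with vehicle, relative to the 75th percentile. Rab3a stood at 1.30 ± 0.06 (SD, n = 3) untreated, −1.01 ± 0.21 (SD, n = 2) with vehicle and 1.21 with 4OHT (n = 3). Rusc2 stood at 1.44, −0.97 and 1.24, Mllt11 at 2.42, −0.50 and 2.20, and Plk3 at 2.59, 0.77 and 2.86. Others stood between, such as Fgf4 (6.50, 2.87 and 4.22). In contrast Slbp stood at 2.68, 2.19 and 0.45, Rit1 at 2.42, 1.70 and 0.02 and Med4 at 3.77, 2.70 and 0.89. Relative to the 75th percentile, each of these 3 was further below vehicle with 4OHT than vehicle was below untreated. For Med4 that holds on 1 of its 2 probes (the other read −1.01 for vehicle against untreated and −0.55 for 4OHT against vehicle). On the spike-in scale every gene named here would lie lower in both treated groups, by the shifts in the 75th percentile of −1.28 and −1.58. There 4OHT against vehicle shifts by −0.31, so the order turns for Med4, is near a tie for Rit1 and holds for Slbp.

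The difference between 4OHT and vehicle arrays could come from the slide: for bright genes slide and 4OHT cannot be told apart, because 0 slides hold both groups. Chemosensory receptor probes, 1492 in number and mostly dim, spread less between slides (SD 0.68, 4OHT minus vehicle) than within slide 2 (SD 0.78, vehicle minus untreated). The ratio of 0.875 (95% bootstrap interval over probes, not arrays, 0.826 to 0.927; 0.923 without untreated replicate 2) met the bound set against a slide difference. That bound was wrong, because the second difference also carries actinomycin D and the slide row. Single pairs of arrays spread by 0.78 to 1.0 between slides, 0.68 to 0.73 within the 4OHT and 0.81 within the vehicle group, so a slide difference stays open for dim genes. Of these probes, 184 were well above background on every slide 2 array and 131 on every slide 1 array. That difference could come from the slide or from 4OHT. After cyclic loess 100% of the 997 called genes kept their direction with an unadjusted p under 0.05, and 710 an adjusted one. The unadjusted threshold is looser than the one that called these genes, so the 100% cannot decide on a trend with intensity. Loess moved the median difference from 0.78 to 0.8 for the higher genes and from −0.89 to −0.85 for the lower genes. A trend that loess removes therefore accounts for little of these medians.

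A hypothesis for the genes higher with 4OHT is that their mRNA was lost more slowly. Of these 263 genes, 47.9% were lower in the 5 actinomycin D arrays than untreated, against 18.8% of all genes. That share cannot decide whether they stood out only because other mRNAs were lost further with 4OHT. It was also high among the genes lower with 4OHT, and the 263 were brighter (median signal 0.16, against −1.14 for all genes). On the spike-in scale 35 of the 263 were still called higher than vehicle. Slower loss without new transcription may apply but stays open. On the spike-in scale 3 of the 263 lay above untreated at an adjusted p under 0.05 (1.14%). All 3, Prob1 included, were below background in untreated and so had no measured untreated level. A further 257 lay below untreated there, but that scale moves every gene by the same −1.58 and called 26622 of the 28491 genes lower. The 257 therefore largely restate the shift. Relative to the 75th percentile, 94 of the 263 were called above untreated and 85 below, and a rise there can be a smaller loss. Of the 734 genes lower with 4OHT, 67.8% were lower after actinomycin D. Over all genes the slope of 4OHT minus vehicle on that loss was 0.054 (95% bootstrap interval over genes 0.048 to 0.061, r = 0.12 across genes). The interval carries no spread between arrays, and the slope was too shallow to decide whether further loss accounts for the 734 genes. The slide remains open for both sets.

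More genes were called higher than lower after actinomycin D, and a candidate explanation is the scaling to the 75th percentile. Of the 11831 genes called higher with vehicle, 96.4% lay below untreated on the spike-in scale, but that scale moves every gene by the same −1.28, so the share restates this shift and leaves the explanation open. The shift itself rests on spike-in probes that differed by −0.08 to 0.32 between these groups. No biological explanation of the split was tested. For 4OHT against untreated, 1 of the 10 splits of the 6 arrays, the real one, called as many genes (17169, against 0 as the highest of the others), and 10 splits are too few for a share under 0.05.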
